A study of Mus musculus with 4 samples.

How the data were processed

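The series measured RNA of NMuMG cells, a normal mouse mammary gland epithelial cell line, on Affymetrix exon arrays. Per the labels' protocols, the cells were grown in DMEM (glucose at 4.5 g/l) to which fetal bovine serum (10%) and insulin (10 ug/ml) were added. They were either left untreated or given 1 ng/ml recombinant human TGF-beta1, a growth factor that can turn epithelial cells towards a mesenchymal form, for 24 h. Total RNA was isolated on RNeasy columns and labelled with biotin, per the labels. The 4 columns of deposited values describe both conditions at gene level (23332 transcript clusters) and at exon level (229581 probesets, each covering an exon or a part of one). The design text speaks of only 2 samples, so the gene level and the exon level were read as summaries of the same cultures and never as replicates of each other. Each group therefore held 1 array at each level.

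The deposited values were intensities on a linear scale, already summarised by the authors per transcript cluster or per probeset. The background correction, normalization, probe summary, software and genome build are not given in the sources used here. The quantiles of the untreated and the TGF-beta columns differed, so the columns had not been made identical after the summary. The deposited gene-level intensities had a median of 130.1 in the untreated and 120.1 in the TGF-beta column and ranged from 3.76 to 18284. Those at exon level had medians of 297 and 239.5. Because no background or detection value was used here, signal near the lower end of this scale could not be told from background. With 1 array per group, the number of arrays limits the precision of every difference, and no p-value was computed.

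Gene names came from the platform annotation. Of the gene-level clusters, 14996 had 1 symbol, 1019 had several and 7317 had none. Of the exon-level probesets, 209279 had 1 symbol, 4446 had several and 15856 had none. Clusters and probesets with several symbols or none were not named. Symbols were updated through a RefSeq gene table of assembly GRCm38.p6, used for names only. At gene level 14941 clusters were matched by gene identifier, 28 by symbol and 27 by synonym. At exon level 184498 probesets were matched by symbol, 24312 by a synonym that belonged to 1 gene, and 469 kept the symbol of the annotation. No coordinates or exon numbers are given, because the build of the arrays was not named and the probesets carried no positions.

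Values were transformed as log2(intensity + 1), and each difference is TGF-beta minus untreated on that scale. The pseudocount makes the differences of dim genes slightly smaller. A feature was at level when the larger of its 2 intensities was at or above the median of all values of that level, which was 124 for genes and 265 for probesets. A feature could thus be at level through 1 array and lie below the rule in the other, and the size of its difference is then uncertain. Where a symbol had several clusters, the cluster with the highest mean was used. This left 14847 genes, of which 9159 were at level. A gene was counted as higher or lower when its log2 difference was at least 1 in size, which is a 2-fold difference. At exon level, the median and the standard deviation (SD) of a gene's probesets at level gave the spread within the gene, which is a spread between parts of a transcript and not between cultures.

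For 30 gene lists, the median difference of the members at level was set against 10000 random lists of the same size. Random members were drawn, with replacement, from genes of the same 1 of 20 bins of mean level. A list was called apart when its median lay outside the central 95% of the random medians. These percentiles describe the 2 arrays and not the conditions. Lists with fewer than 3 members at level were not tested, which left 28 tested lists. The splicing index of a probeset was its difference minus the median difference of the other probesets of its gene, for probesets at level in genes with at least 5 of them. A probeset with an index of at least 1 in size was called departing.

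The lists, the rules of size and level, the alternatives and the genes to name were fixed before the data were examined. Named genes were the 12 largest differences each way among genes at level with at least 3 probesets at level, of which at least 75% lay in the gene's direction. This rule could choose among 6368 genes. To these were added 2 to 4 members of each list with the largest differences, a fixed set of genes always named (Cdh1, Vim, Fn1, Snai1, Zeb1, Zeb2, Esrp1, Esrp2, Smad7, Fgfr1 and Fgfr2, beside 1 that is not reported here), the 10 probesets with the largest and the 10 with the smallest splicing index, and the probeset with the largest index in size in each gene of a splicing list. Other genes were chosen after their values were seen and are said to be so.

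The alternatives were other level rules, centring on the median difference, quantile normalization, removal of a lowess curve (span 0.3) of difference on mean level, exon-level medians in place of gene-level values, a pseudocount of 16, other sizes, unmatched random lists, list means, and the mean of all clusters of a symbol. The calculations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and the plots were drawn with matplotlib 3.10.9. Intervals of shares and of ratios of counts were exact 95% binomial intervals and treat genes or probesets as independent. The size rule was tested on simulated data for the gene-level comparison. The noise SD of 0.446 was taken from the spread of the real differences after removal of the lowess curve. Of 200 genes moved by 1.5 on the log2 scale, 85.0% passed the rule, beside 226 false calls among 9072 genes. Of 200 genes moved by 3, 99.5% passed, beside 234 false calls among 9089 genes. For the splicing index, with a noise SD of 0.298 and 108360 probesets, 96.0% of 200 probesets moved by 1.5 were recovered, beside 182 false calls. In both simulations the noise was centred on 0 and equally wide at all levels. The real differences of genes at level had a median of −0.27, and dim probesets departed more often than bright ones. These counts of false calls therefore do not estimate those among the real calls.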

Results

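Gene expression was compared between untreated NMuMG mouse mammary epithelial cells and NMuMG cells given 1 ng/ml TGF-beta1 for 24 h. Each condition was represented by 1 array, read at gene level and at exon level, so the differences below have no replicate check. The SD given with a gene is the spread between its exon-level probesets and does not measure the spread between cultures. Across genes at level, the untreated and TGF-beta arrays differed by a median of −0.27 on the log2 scale. Across all transcript clusters the median difference was −0.14, and the Pearson correlation of the log2 intensities was 0.966.

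The comparison asked which genes differed in level after 24 h of TGF-beta. The largest higher values with TGF-beta were those of the hyaluronan synthase Has2, the cathepsin Ctsw and the cytokine Il11. The largest lower values were those of the aldo-keto reductase Akr1c19, the sulfotransferase Sult1c2 and the lectin Lgals4. Among the gene lists, the medians of mitosis, DNA replication and epithelial junction genes were lower than in random lists, while those of collagens, actin cytoskeleton genes and growth factors were higher. Of the 9159 genes at level, 209 were at least 2-fold higher and 797 at least 2-fold lower with TGF-beta. Higher genes thus made up 20.8% of all genes past the size rule, a share that depended on how the arrays were scaled. It was 32.7% after centring (269 higher, 554 lower), 45.7% after quantile normalization (339 and 403) and 43.0% after removal of the trend of difference on level (330 and 437). With genes ordered by mean level into 10 equal groups, the median difference was 0.29 in the fourth and −0.45 in the sixth group, as the plot of difference against mean intensity shows.

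**Figure D1:**
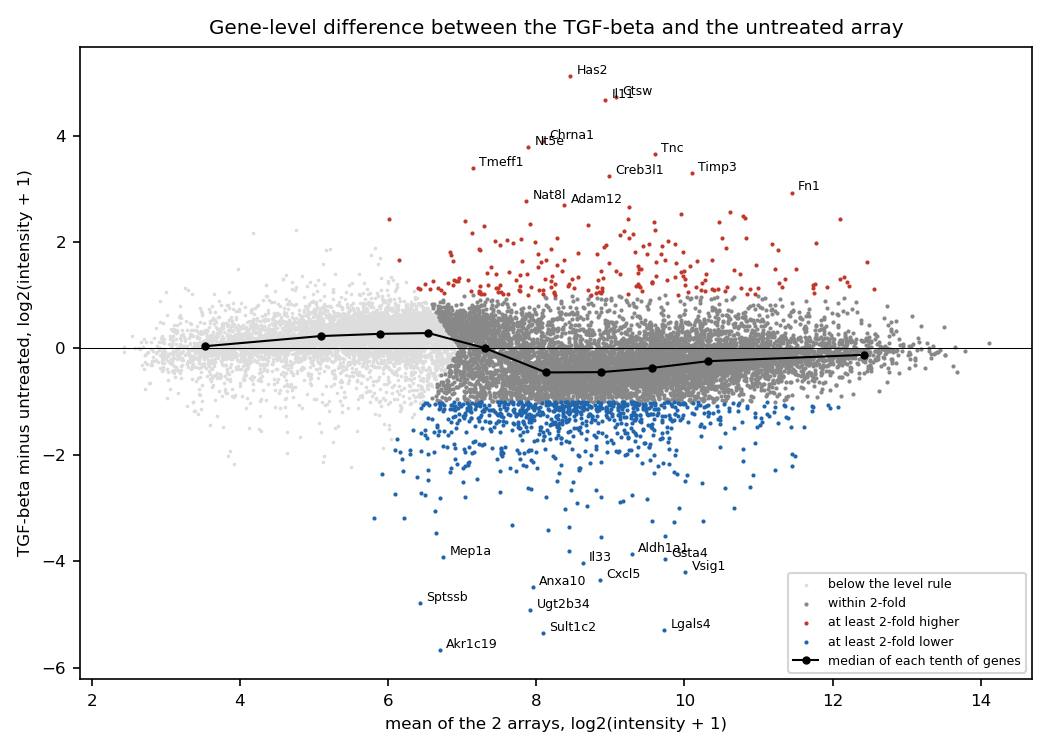
Each point is a gene, with the mean log2(intensity + 1) of both arrays on the x axis and the log2 difference, TGF-beta minus untreated, on the y axis. Red and blue points are the 209 higher and 797 lower genes, pale points lie below the level rule, and the black line joins the medians of 10 equal groups of genes by mean level, from 0.29 in the fourth group to −0.45 in the sixth.

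Has2 (transcript cluster 6835856), which makes the matrix polysaccharide hyaluronan, had the largest higher value. Its intensity was 58.7 in untreated and 2081 in TGF-beta cells, a log2 difference of 5.12, and its 6 probesets had a median difference of 4.98 ± 0.67 (SD). Ctsw, a cathepsin protease, followed with a difference of 4.72 (105 to 2778). Il11 (transcript cluster 6973206), a cytokine of the interleukin-6 family, had 95.5 in untreated and 2461 in TGF-beta cells, a difference of 4.67. Among matrix genes, the glycoprotein tenascin C (Tnc) differed by 3.65 ± 0.73 over 29 probesets, the metalloprotease inhibitor Timp3 by 3.30 ± 0.36 over 12, and the metalloprotease Adam12 by 2.69 ± 0.68 over 26. Fibronectin (Fn1, transcript cluster 6759621) was already bright in untreated cells at 1013 and had 7731 with TGF-beta, a difference of 2.93. All 54 of its probesets were higher, with an SD of 0.48. The remaining genes of the 12 were the acetylcholine receptor subunit Chrna1 (3.90), the ecto-nucleotidase Nt5e (3.78), the transmembrane protein Tmeff1 (3.39), the transcription factor Creb3l1 (3.24) and the N-acetylaspartate synthase Nat8l (2.77). In untreated cells, the intensities of Tmeff1 (42.9), Has2 (58.7), Nt5e (63.1) and Chrna1 (69.6) lay below the 124 of the level rule, as did those of others of the 12, so the exact size and order of these differences are uncertain.

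At the other end, Akr1c19 (transcript cluster 6804526) had 739.8 in untreated and 13.5 in TGF-beta cells, a log2 difference of −5.67 with 7 probesets at −5.85 ± 0.71 (SD). Sult1c2 differed by −5.35 and the glucuronosyltransferase Ugt2b34 by −4.91. The glutathione transferase Gsta4 differed by −3.95 and the retinaldehyde dehydrogenase Aldh1a1 by −3.86. Galectin-4 (Lgals4, transcript cluster 6959460), a lectin of gut epithelium, was among the brighter genes in untreated cells at 5310 and had 135 with TGF-beta, a difference of −5.29. The annexin Anxa10 differed by −4.49, the surface protein Vsig1 by −4.19 and the metalloprotease meprin alpha (Mep1a) by −3.92. The neutrophil-attracting chemokine Cxcl5 (−4.35), the alarmin cytokine Il33 (−4.04) and Sptssb (−4.78), a subunit of the enzyme that starts sphingolipid synthesis, completed the 12 lowest. With TGF-beta, the intensities of Akr1c19 (13.5), Sptssb (15.5) and Mep1a (26.5) lay near the lower end of the scale, and those of Sult1c2 (41.7), Ugt2b34 (43.1) and Anxa10 (51.4) not far above, so the exact size and order of these differences are uncertain. All probesets at level of these 12 genes were lower with TGF-beta, and all those of the 12 highest genes were higher, as the plot of named genes at both levels shows.

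**Figure D2:**
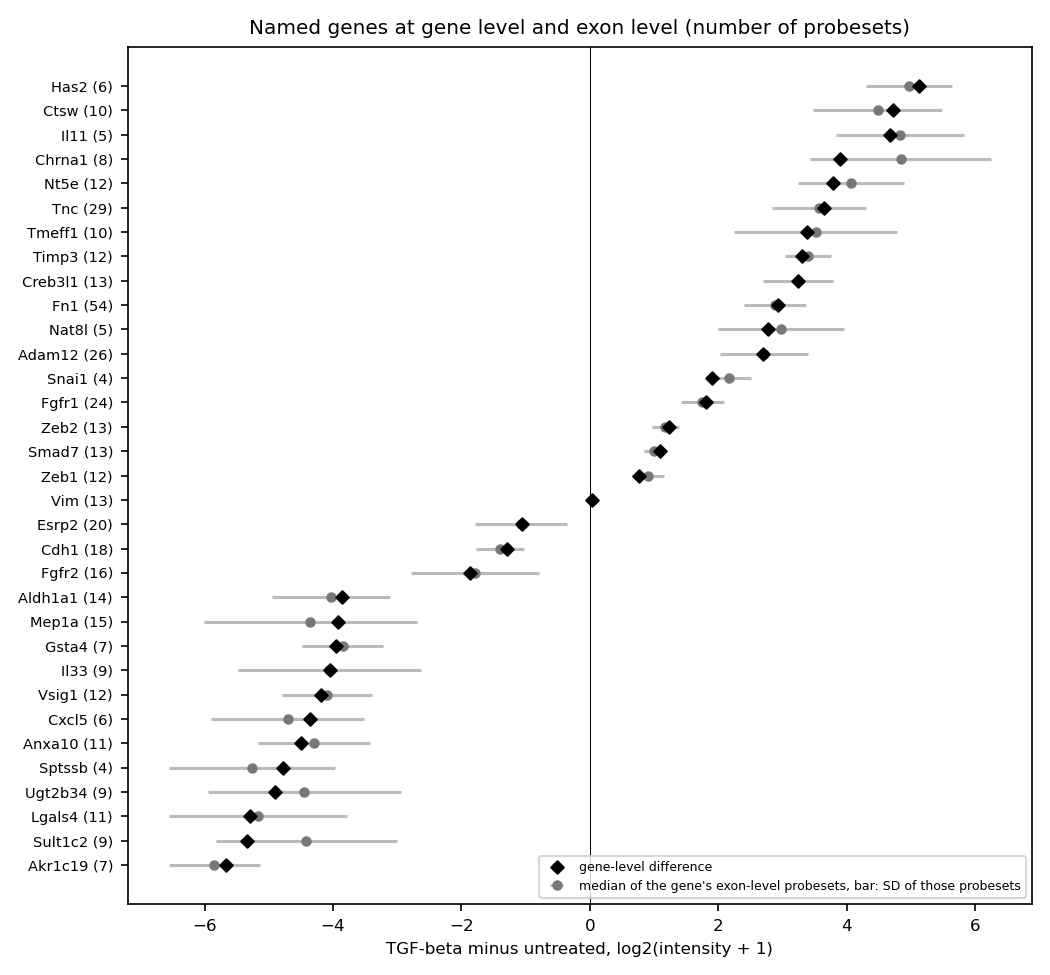
Log2 difference, TGF-beta minus untreated, of the 12 highest and 12 lowest genes and of genes always named that had probesets at level; diamonds are gene-level values, circles the median of the gene's exon-level probesets and bars 1 SD of those probesets, with their number in brackets. Has2 stands at 5.12 and Akr1c19 at −5.67, while Vim stands at 0.03 with a probeset SD of 0.09.

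Of the 28 tested lists, 11 stood apart on the higher side of random lists of like level and 5 on the lower side. All 19 TGF-beta response genes measured were at level; 7 were at least 2-fold higher, none lower and 12 within 2-fold. The list's median of 0.58 stood above all 10000 random lists, whose median was −0.19. Examples were Ldlrad4, a dampener of TGF-beta signalling (1.92), the circadian repressor Bhlhe40 (1.89), the matricellular protein Ccn2 (3225 to 9974, 1.63) and the Smad co-repressor Skil (1.15). Smad7, an inhibitor of the pathway, differed by 1.09 ± 0.16 (SD, 13 probesets). Of the 4 Id genes, inhibitors of helix-loop-helix transcription factors, 3 were at least 2-fold lower, and the median of −1.84 was at percentile 0.02. Id2 differed by −2.03 (5819 to 1429), Id1 by −1.89 and Id3 by −1.78, whereas Id4 differed by 0.30.

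Among 12 transcription factors of the epithelial-mesenchymal transition (EMT), 2 were at least 2-fold higher, none lower and 10 within 2-fold, with a median of 0.20 at percentile 99.9, or 0.42 after the trend of difference on level was removed. The 2 were Snai1 (transcript cluster 6883321; 249.7 to 936, 1.90) and Zeb2 (493 to 1165, 1.24), both repressors of E-cadherin. Zeb1 differed by 0.77, the high-mobility-group factor Sox4 by 0.80 and the homeobox factor Prrx1 by −0.79. With the trend removed, Zeb1 (1.14) and Sox4 (1.18) passed the size rule as well, and Prrx1 was at −0.42. Of 19 epithelial junction genes at level, 1 was higher, 8 were lower and 10 lay within 2-fold, with a median of −0.73 at percentile 0.04. E-cadherin (Cdh1, transcript cluster 6978923), the main adhesion protein of epithelial cells, had 4153 in untreated and 1698 in TGF-beta cells. Its gene-level difference was −1.29, and all 18 of its probesets were lower, at −1.40 ± 0.37 (SD). Periplakin (Ppl, −2.86), the epithelial transcription factor Ehf (−2.45) and the polarity protein Crb3 (−1.98) were lower by more, though Crb3 had 2 of its 6 probesets higher. With TGF-beta, Ehf (61.6) and Crb3 (91.2) lay below the level rule, so the sizes of their differences are uncertain. The claudin Cldn4 was the member that was higher, at 2.66 over only 2 probesets. Without the level rule, which lets in members near the lower end of the scale, the junction list had a median of 0.07 and no longer stood apart.

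Keratins, the intermediate filament proteins of epithelia, went both ways. Of 4 at level, Krt19 was lower (4612 to 578, −2.99), and Krt20 (0.93), Krt17 (0.60) and Krt18 (0.20) lay within 2-fold. Their median of 0.40 stood apart at percentile 97.8, but this call was lost in 9 of 12 alternatives, and the mean was −0.32. The 11 mesenchymal markers at level had 5 higher, none lower and 6 within 2-fold, with a median of 0.96 above all random lists. Without the level rule the median was 0.42, and it still stood apart. Besides Fn1 and Tnc, the fibronectin receptor subunit Itga5 (751 to 4211, 2.49) and the secreted glycoprotein Fstl1 (1.77) were higher. In untreated cells Fstl1 was at 61.8, below the level rule, so the size of its difference is uncertain. Vimentin (Vim), the intermediate filament of mesenchymal cells, was among the brightest genes in both conditions at 12687 and 12991, a difference of 0.03 ± 0.09 (SD, 13 probesets), or −0.06 after the trend of difference on level was removed.

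**Figure D3:**
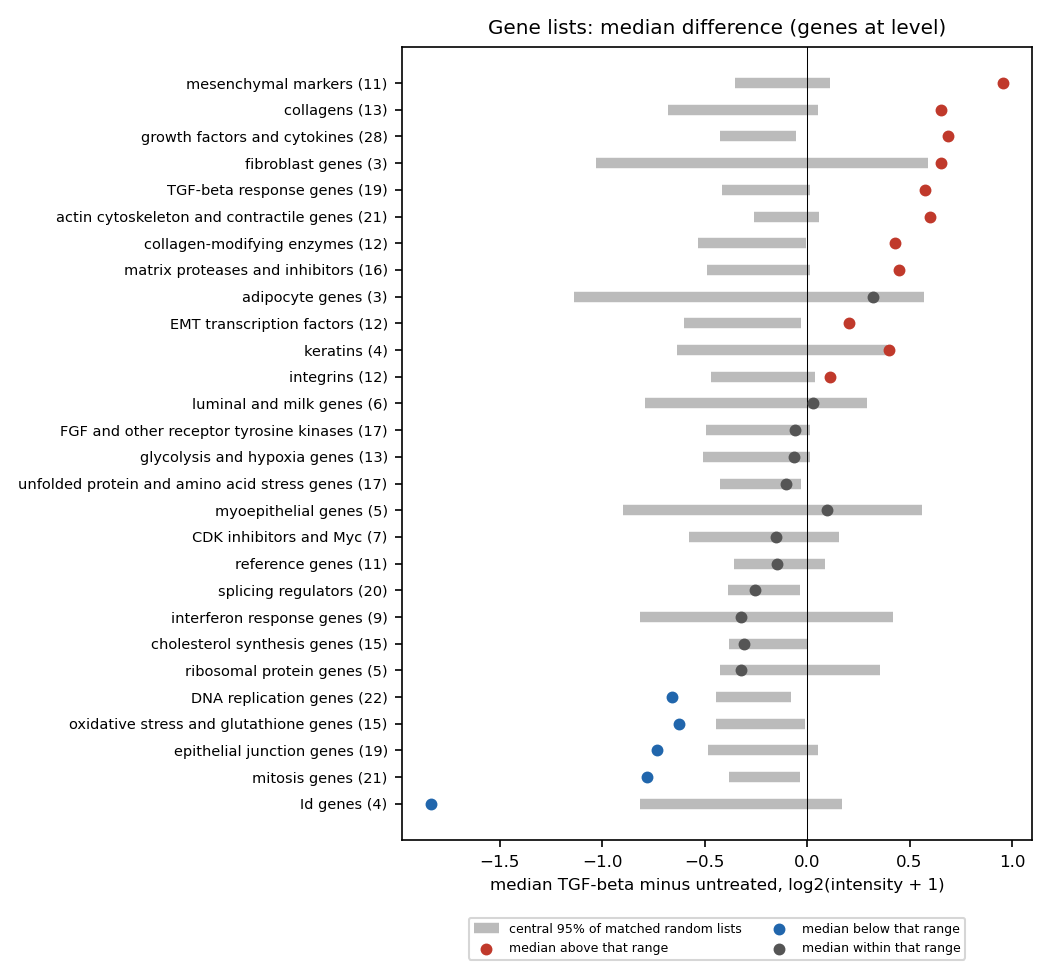
Median log2 difference, TGF-beta minus untreated, of the members at level of each tested list (dots; number of members in brackets), beside the central 95% of 10000 random lists matched on level (grey bars). Red dots are the 11 lists above that range and blue dots the 5 below it; mesenchymal markers stand at 0.96 and Id genes at −1.84.

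Matrix and cytoskeleton lists stood apart on the higher side. Of 21 actin cytoskeleton and contractile genes, 3 were higher, 1 lower and 17 within 2-fold, with a median of 0.60. Smooth muscle actin (Acta2, 1.88), the stress fibre protein Pdlim7 (1.47) and the focal adhesion protein zyxin (Zyx, 1.22) were higher, and the myosin kinase Mylk was lower (−1.76). Acta2 in untreated cells (77.1) and Mylk with TGF-beta (75.8) lay below the level rule, so the sizes of their differences are uncertain. Mylk also had 2 of its 11 probesets higher. Of 13 collagens, 4 were higher and 9 within 2-fold, with a median of 0.65; the 4 were Col12a1 (1.56), Col7a1 (1.40), Col5a1 (1.09) and Col5a3 (1.07). With a level rule at the 75th percentile the collagen median was 0.18, and the list no longer stood apart. Among 12 collagen-modifying enzymes, 2 were higher and 10 within 2-fold, with a median of 0.43. These were the procollagen protease Bmp1 (1.19) and the lysyl hydroxylase Plod2 (1.13), beside values of 0.72 and 0.61 for the crosslinking oxidases Loxl2 and Loxl1. Matrix proteases and their inhibitors had 4 of 16 higher, 1 lower and 11 within 2-fold, with a median of 0.45, or 0.77 after quantile normalization. The gelatinase Mmp9 was higher (1.29, from an untreated intensity of 75.2 below the level rule) and the collagenase Mmp13 lower (1171 to 293, −2.00). Of 12 integrins, 3 were higher, 1 lower and 8 within 2-fold, with a median of 0.11 at percentile 99.2. Itga5, Itgb3 (1.29) and Itga2 (1.11), all parts of matrix receptors, were higher, and the leukocyte integrin subunit Itgb7 was lower (−2.18). The integrin median varied with the level rule and was 0.29 without one, 0.55 with the mean as rule and 0.60 at the 75th percentile. It was 0.05 from the probesets at level, and the call was lost after the trend of difference on level was removed (percentile 95.3).

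Growth factors and cytokines had the most members past the size rule. Of 28 at level, 10 were higher, 4 lower and 14 within 2-fold, and the median of 0.69 stood above all random lists. Besides Il11, the activin subunit Inhba was higher (885 to 3742, 2.08). Fgf1 (731 to 130.0, −2.48), a ligand of fibroblast growth factor receptors, and the neutrophil chemokine Cxcl1 (−2.02) were lower, though Cxcl1 had 2 of its 5 probesets higher. Of 17 receptor tyrosine kinases, 1 was higher, 3 lower and 13 within 2-fold. Their median of −0.06 did not stand apart and changed sign in 5 alternatives, all 3 scalings among them. Fgfr1 (transcript cluster 6974743) was the higher member, at 541 in untreated and 1891 in TGF-beta cells (1.80 ± 0.34, SD of 24 probesets). Fgfr2 (transcript cluster 6971490), of the same receptor family, was lower (351 to 95.8, −1.86), as were the neuregulin receptor Erbb3 (−1.28) and the ephrin receptor Ephb3 (−1.27). With TGF-beta, Fgfr2 and Erbb3 (74.2) lay below the level rule, so the sizes of their differences are uncertain.

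Both proliferation lists were lower. All 21 mitosis genes had differences below 0, with 6 at least 2-fold lower, 15 within 2-fold and a median of −0.78, below all random lists. The proliferation marker Mki67 (636 to 202, −1.65), the spindle checkpoint kinase Ttk (−1.34), the anaphase activator Cdc20 (−1.26) and the chromosomal passenger Birc5 (−1.05) were the largest. With the trend of difference on level removed, Mki67 (−1.25) stayed past the size rule, while Ttk (−0.97), Cdc20 (−0.97) and Birc5 (−0.67) lay within 2-fold. All 22 DNA replication genes also lay below 0, with 3 at least 2-fold lower and a median of −0.66 at percentile 0.01, or −0.44 after quantile normalization. The primase Prim1 (−1.38), the helicase component Gins1 (−1.14) and the loading factor Mcm10 (−1.04) passed the size rule, and thymidylate synthase (Tyms) was at −0.99. After the trend of difference on level was removed, Prim1 (−1.01) still passed the rule, but Gins1 (−0.74) and Mcm10 (−0.68) did not. Both medians stayed below 0 and apart in every alternative tried. Of 7 cyclin-dependent kinase inhibitors and Myc genes, 1 was lower and 6 lay within 2-fold, and the median of −0.15 did not stand apart and turned positive in 4 alternatives. Cdkn2c was lower (−1.42), while Cdkn1b (−0.66), Cdkn2b (0.47) and Cdkn1a (−0.30) lay within 2-fold.

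Of the metabolic and stress lists, that of oxidative stress and glutathione genes stood apart, on the lower side. It had 5 of 15 members at least 2-fold lower, 10 within 2-fold and a median of −0.63 at percentile 0.05. Besides Gsta4, these included the catalytic subunit of the glutathione-making ligase, Gclc (3413 to 922, −1.89), the microsomal transferase Mgst1 (−1.41) and the cystine transporter Slc7a11 (−1.15). Glycolysis and hypoxia genes had 2 of 13 lower, the oxygen-sensing hydroxylase Egln3 (1926 to 270.5, −2.83) and the pyruvate dehydrogenase kinase Pdk1 (−1.06), beside hexokinase Hk2 at 0.82 and Ndrg1 at 0.71. After the trend of difference on level was removed, Egln3 (−2.47) stayed lower, Pdk1 (−0.87) lay within 2-fold and Hk2 (1.22) passed the size rule. Of 17 unfolded protein and amino acid stress genes, the mTORC1 inhibitor Ddit4 was higher (1.40) and the endoplasmic reticulum protein Herpud1 lower (−1.06), beside Psat1 (−0.94) and Sesn2 (−0.85). The medians of these lists, −0.07 and −0.11, did not stand apart and turned positive under all 3 scalings. All 15 cholesterol synthesis genes lay within 2-fold, with Lss at −0.59, Stard4 at −0.57, Ebp at −0.48 and Dhcr7 at −0.41, and their median of −0.31 did not stand apart (−0.14 after quantile normalization and −0.10 after removal of the trend). Among 9 interferon response genes, Oasl2 was higher (1.26, with 5 probesets at 2.34) and Ifit2 lower (−1.79, 1 probeset), Stat2 was at −0.83 and Ddx58 at −0.57, and the median of −0.32 did not stand apart (−0.0017 and −0.05 after the same steps).

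Splicing regulators had 4 of 20 members lower and 16 within 2-fold, and their median of −0.25 was at percentile 28.9 (−0.12 after quantile normalization and −0.10 after removal of the trend). The RNA-binding protein Rbm47 was lower by most (2875 to 301, −3.25 with 7 probesets at −3.34 ± 0.57, SD). Esrp2, a regulator of epithelial exon choice, had 1416 in untreated and 682 in TGF-beta cells (−1.05), with 17 of 20 probesets lower. Its paralog Esrp1 was below the level rule in both (25.9 and 37.6). Celf2 was at −1.02, and Srsf3 at −1.07 with 13 probesets at −0.08 ± 0.47 (SD), so the 2 levels differed for Srsf3. After removal of the trend, Esrp2 (−0.76), Srsf3 (−0.67) and Celf2 (−0.62) lay within 2-fold, and only Rbm47 (−2.95) stayed lower among the 4. The mean of the list, −0.46, stood apart at percentile 2.13 where the median did not.

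Lists for cell types of the gland gave few members at level. Of 6 luminal and milk genes, the mucin Muc1 was lower (3744 to 393, −3.25), while Aqp5 (−0.35, but 0.06 after quantile normalization and 0.02 after removal of the trend), Gata3 (0.33) and Cited1 (0.29) lay within 2-fold, and the median of 0.03 did not stand apart and turned negative in 2 alternatives. Of 5 myoepithelial genes, 2 were higher and 2 lower, with a median of 0.10 at percentile 56.0 and a mean of −0.02. The Notch ligand Dll1 was at 1.01 and the stem cell receptor Lgr5 at −1.32, though the 4 probesets of Lgr5 had a median of −0.20. Fibroblast genes had 3 members at level, all within 2-fold, and a median of 0.65 at percentile 98.6. These were Col1a1 (199 to 389, 0.97), Col1a2 (127 to 199.9, 0.65) and Fbln1 (0.17), of which both collagens also belong to the collagen list. From probesets at level the list's median was 0.64 at percentile 93, and it no longer stood apart. Fibroblast genes that are no collagens had a median intensity of 52.3 in untreated and 61.4 in TGF-beta cells, and 8 of 9 lay below the level rule with TGF-beta. The 3 adipocyte genes at level were Pparg (−1.21), Plin1 (0.73) and Cidec (0.32), with a median of 0.32 that did not stand apart and a mean of −0.05. Endothelial genes had 1 member at level, Eng at 0.53, and leukocyte genes 2, the lipopolysaccharide co-receptor Cd14 at −1.04 and Cd68 at −0.73, so neither list was tested.

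Reference genes gave a scale for these values. All 11 lay within 2-fold, with a median of −0.15 that did not stand apart, and ranged from Tfrc at −0.78 and Hprt at −0.71 to B2m at 0.42. The ribosomal protein genes had a median of −0.32 and 4 of 5 members within 2-fold, among them Rpl10a (−0.37), Rpl8 (−0.32) and Rps3 (−0.19). Rpl4 was more than 2-fold lower at gene level (155 to 38.4, −1.99), but its 13 probesets had a median of −0.07 ± 0.13 (SD), and the reference gene Rplp0 was likewise at −0.56 against −0.02. Medians of both lists kept their sign under all scalings but were nearer 0, at −0.06 and −0.19 after quantile normalization and −0.08 and −0.16 after removal of the trend.

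A further comparison set the exon level beside the gene level. Across 8270 genes with at least 3 probesets at level, the Spearman correlation between the gene-level difference and the probeset median was 0.955. Genes are not independent replicates, and both levels summarise the same samples. All 923 genes past the size rule had a probeset median of the same sign, and for 912 the difference was larger than the SD of the gene's probesets. The levels were more than 1 log2 unit apart for 25 genes, 12 of them past the size rule.

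The exon level also asked which probesets departed from the rest of their gene, as a switched exon would. In genes known to switch exons between epithelial and mesenchymal cells, Fgfr2, Epb41l5 and Fn1 had probesets departing both ways. Those of Cd44 fell into a lower and a higher set. The catenin Ctnnd1 had no departing probeset among 22. Over all 8038 genes tested, 2191 of 108360 probesets had a splicing index of at least 1 and 1752 of −1 or less. These lay in 2361 genes, 29.4% of those tested. Of 42 genes of the splicing list, 38 could be tested and 16 had a departing probeset, a share of 42.1% against a median of 36.8% in random lists matched on the number of probesets. The share was at percentile 76.6, within the central 95% of random lists (21.1% to 52.6%). Probesets carried no positions, so no departing probeset was tied to a known exon, and departing calls were more frequent among dim probesets (7.39% in the dimmest and 1.08% in the brightest of 4 equal groups).

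Cd44, a hyaluronan receptor with a block of variable exons, was split into separate sets of probesets. Of its 19 probesets, 9 departed downwards with differences from −1.68 to −0.84, 9 did not depart and had differences from 0.23 to 0.59, and 1 departed upwards at 0.74. For each higher probeset, the median of the others lay in the gap between the lower and the higher set. The upward call therefore marks the top of the higher set and not a further set. Probeset 4534496 had the largest index in size, −1.93 (466 to 144), or −0.80 when set against the gene-level value. The gene-level value of −0.88 lay within the range of the lower set. Which of the 2 sets departed thus depended on the value used for comparison. Of 16 probesets of Fgfr2, whose alternative exons set ligand choice, 4 departed downwards (−3.29 to −2.87) and 2 upwards. Probeset 4523298 had 1882 in untreated and 2343 in TGF-beta cells, a difference of 0.32 and an index of 2.16, where the other 15 had a median of −1.84.

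Of the other splicing-list genes with higher departing probesets, the polarity regulator Epb41l5 had 5 upwards and 3 downwards of 25, with a largest index of 1.64 for probeset 5440374 (814 to 1259). Scrib, also a polarity protein, had 3 upwards of 43, with an index of 1.52 for probeset 5375133 (2512 to 4462). In Fn1, probeset 5201971 went from 149 to 4070.2 and had an index of 1.89 above the already higher rest of the gene, while probeset 4630426, named after its value was seen, had an index of −1.26 at a difference of 1.63. Single probesets departed upwards in the laminin receptor subunit Itga6 (1.40), the nucleotide exchange factor Arhgef11 (1.35) and the kinase Map3k7 (1.17), and 2 did in Ralgps2 (up to 1.30). Downwards, single probesets departed in Lrrfip2 (−1.80), the polarity protein Pard3 (−1.39), the actin regulator Enah (−1.20), Dlg1 (−1.14), the kinase Slk (−1.09), the spectraplakin Macf1 (−1.06) and the transcription factor Tcf7l2 (−1.03). The indices of Enah, Slk, Macf1 and Tcf7l2 were smaller than 1 in size after the trend of difference on level was removed, at −0.99, −0.95, −0.95 and −0.91. In turn, the largest index of the tropomyosin Tpm1, 0.94, became 1.04 after that removal and 1.02 after quantile normalization, which would make its probeset a departing one. For Ctnnd1 the largest index in size was −0.53.

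**Figure D4:**
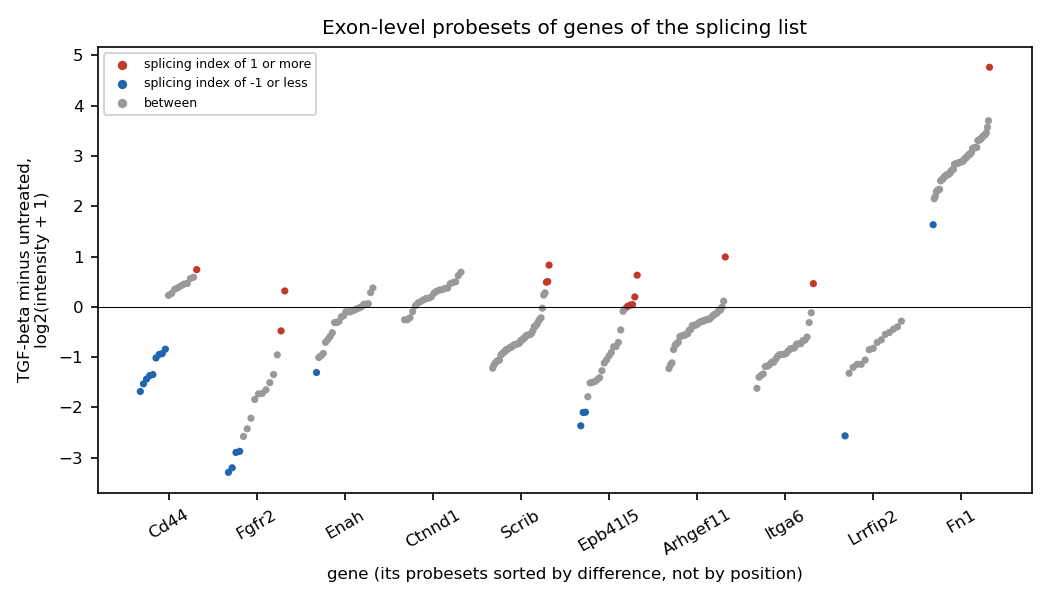
Log2 difference, TGF-beta minus untreated, of each exon-level probeset at level in 10 genes of the splicing list, sorted by difference within each gene. Red and blue points have a splicing index of at least 1 and of −1 or less; Cd44 has 9 blue points between −1.68 and −0.84 and 9 grey points between 0.23 and 0.59, and Ctnnd1 has no coloured point.

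Across all genes, the largest splicing indices belonged to the collagens Col5a3 (4.63, probeset 4936268, 7.25 to 400.0) and Col7a1 (4.02 and 3.41) and to the cytochrome Cyp2s1 (4.48). Ugt2b34 (3.96), Itih2 (3.61), Mep1a (3.49), the transcription factor Hnf4a (3.45), the haem carrier Hpx (3.39) and Pear1 (3.32) followed. In Cyp2s1, Hnf4a and Hpx the named probeset was higher with TGF-beta (1.19, 0.85 and 0.96) while the median of the gene's other probesets was −3.30, −2.61 and −2.43. The smallest indices were those of the actin nucleator Cobl (−5.05, probeset 5236142, 279 to 7.81), the kinesin Kif12 (−4.82), Igfbp5 (−4.54), Mtcl1 (−3.70), the keratin Krt14 (−3.70) and Chrna1 (−3.55). Prss46 (−3.51), En1 (−3.12), Barhl2 (−3.11) and Slc25a48 (−3.10) followed. Several of these values rest on an intensity near the lower end of the scale in 1 array, among them those of Col5a3 (7.25), Cobl (7.81) and Igfbp5 (5.59), so their exact size and order are uncertain. Set against the gene-level value, the indices of Itih2 and Slc25a48 were 2.25 and −1.95. For Krt14 the probeset had 1991 in untreated and 198 in TGF-beta cells, while its other probesets had a median difference of 0.37 ± 0.45 (SD).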

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

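Transcript clusters without a gene name took no part in the comparisons, and some of them differed between the arrays. Of 2828 such clusters at level, 56 were at least 2-fold higher with TGF-beta than in untreated cells (1.98%), and 383 were at least 2-fold lower (13.5%). Their median difference was −0.26. Named genes at level had a median of −0.27, with 2.28% at least 2-fold higher and 8.70% at least 2-fold lower. The higher ones included cluster 6876238 (1075 to 5844, a log2 difference of 2.44) and cluster 6942524 (1911 to 10190.3, 2.41). The lower ones included cluster 4791676 (−3.32) and cluster 4751473 (−3.04). No explanation was tested for these clusters.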

How the results depend on the processing

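No list moved from one side of its random lists to the other, although the junction median and the keratin mean changed sign as given below. No replicate could be left out in turn. No paired analysis was possible because each group holds 1 array. The count of genes at least 2-fold higher or lower with TGF-beta was within 1.5 times of 209 and 797 without a level rule, with the mean as level rule, after centring, from exon-level medians and with a pseudocount of 16. It was 121 and 370 with a level rule at the 75th percentile, 339 and 403 after quantile normalization, 330 and 437 after the lowess curve was removed, 572 and 2321 at 1.5-fold and 77 and 218 at 3-fold. After quantile normalization 209 of the higher and 403 of the lower genes were among those counted in the deposited values, and after the lowess 206 and 432. For the splicing index, probesets at 1 or more and at −1 or less numbered 7835 and 8642 without a level rule, 445 and 168 at the 75th percentile, 1355 and 1110 in genes under 2-fold and 235 and 109 at a size of 2. By construction, other level rules and the limit to genes under 2-fold change which features are tested, and other sizes move the threshold. For the other moves the cause was not tested.

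Of 330 list medians and means recomputed, 313 kept their call. Centring moves a list and its random lists alike, so it could not change a call. Lost calls were the junction list without a level rule (0.074), collagens at the 75th percentile (0.18), integrins after the lowess (0.20), the fibroblast list from probesets at level (0.64), and keratins in 9 settings. Keratin medians were 0.20 without a level rule, with the 75th percentile and with the mean as level rule, 0.41 after quantile normalization, 0.34 after the lowess, 0.36 from all probesets, 0.075 from probesets at level and 0.36 with a pseudocount of 16, and the keratin mean was −0.32. Calls gained were interferon genes (−0.29) and adipocyte genes (0.38) without a level rule, myoepithelial genes with the mean as level rule (0.55), and the mean of splicing regulators (−0.46). Between 8 and 11 lists stood apart on the higher side and 5 or 6 on the lower. Of 1195 named-gene values, 120 were counted as moved, as were 12 of 335 values of named probesets. A gene's value was so counted when it moved by more than the SD of the gene's probesets. Genes with 0 or 1 probeset at level, such as Krt17 and Ifit2, had no such SD and were always counted as moved. Named genes past the size rule kept their sign in all 819 of their values, but not all stayed past the rule. Other level rules do not alter a gene's value, and a pseudocount cannot turn the sign of a difference. These settings were therefore no test of the sign. After the lowess, Slc7a11 (−0.86), Herpud1 (−0.86) and Ephb3 (−0.92) were among those that fell within 2-fold. Loxl2 (1.11) and Krt20 (1.18) were among those that passed the rule only then. Differences of features near the lower end of the intensity scale are limited by background, which was not measured separately here.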

Other observations

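The tests of symbol families, of conjugation and detoxification enzymes, of fibroblast genes that are no collagens, and of departing rates in genes on either side of 2-fold were chosen after the results were seen, and the other tests before.

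Medians of genes that share a symbol stem also stood apart, in part through members of the fixed lists and mostly with few genes past the size rule. Of 132 stems with at least 8 genes at level, 9 stood apart on the higher and 10 on the lower side of random lists. By chance 6.6 in all would do so if the genes of a stem varied independently, which was not tested. The Sox transcription factors (12 genes) had a median difference of 0.30 against −0.35 in random lists, and the Wnt ligands (9 genes) 0.50 against −0.23. The Dusp phosphatases (19 genes), some of which switch off mitogen-activated kinases, had 0.28 against −0.24. The Klf transcription factors (11 genes) had a median of 0.14 against −0.24. Of these, 1 Wnt gene was at least 2-fold higher and 1 Dusp and 1 Klf gene at least 2-fold lower, while all Sox genes lay within 2-fold. On the lower side, mitochondrial ribosomal proteins stood out, with medians of −0.54 against −0.29 for 42 Mrpl and −0.58 against −0.35 for 25 Mrps genes, of which 1 and 2 were at least 2-fold lower. Annexins (12 genes, −0.45 against −0.14), Kif motor proteins (20 genes, −0.59 against −0.30) and Rad genes of DNA repair and other functions (15 genes, −0.71 against −0.29) also had lower medians, with 4, 3 and 4 genes at least 2-fold lower and 1 Kif gene higher. These stems stood apart, with the same sign, after quantile normalization and after removal of the lowess as well, as did 7 of the 9 higher and 8 of the 10 lower stems in all. Centring moves a stem and its random lists alike, so it could not change a call. Sizes changed, however: after the lowess the medians were −0.19 for Mrpl, −0.27 for Mrps, −0.35 for Kif and −0.40 for Rad genes, but 0.63 for Sox, 0.76 for Wnt, 0.48 for Dusp and 0.36 for Klf genes. The Zdhhc stem, with a median of −0.02 that was higher than in random lists, turned positive under all 3 scalings. It lay within the random range after quantile normalization and after the lowess (percentiles 95.42 and 95.05). The olfactory receptor stem Olfr (20 genes, 0.36 against 0.05) did not stand apart, at percentile 97.4. Its percentile was 98.6 after quantile normalization and 98.2 after the lowess. No cause was tested for this stem.

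More genes were lower than higher with TGF-beta, 797 against 209, and a difference in scale that depends on intensity was weighed against a true excess. After the lowess of difference on level was removed, the ratio of lower to higher genes was 1.32 (exact 95% interval 1.15 to 1.53), beside 3.81 in the deposited values. Removing that curve brings the median at level from −0.27 to −0.01 whatever its cause, so the ratio moves towards 1 by construction. A difference in the scale of the arrays and a broad lower level of mid-intensity transcripts in the treated cells therefore cannot be told apart, since either gives such a curve. The random lists set beside each gene list share this trend.

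The median of epithelial junction genes was lower (8 of 19 at least 2-fold) and that of actin cytoskeleton genes higher (3 of 21) than in random lists, and fibroblasts in the treated culture were weighed beside the treatment. To give the deposited junction median of −0.73 by dilution alone, other cells would have to make up 39.8% of the treated RNA. The share includes the shift of genes of like level (random-list median −0.20) and would be smaller without it. No single share would give the difference of every member, since 7 of 19 lay above 0 and 12 below. Fibroblast genes that are no collagens had a median intensity of only 61.4 with TGF-beta, below the 124 of the level rule, and 8 of 9 lay below it (exact 95% interval of the share 51.8% to 99.7%), with Dcn at 51.7 and Lum at 22.7 (both named after their values were seen). These values argue against fibroblasts as a large share of the treated culture, if fibroblasts at such a share would bring these genes to level. No fibroblast array was at hand to test that, and leaving out the collagens also removed Col1a1 and Col1a2, which were at level. The treatment stays open, which 1 culture per group cannot separate from other differences between cultures. A small share could not be told apart from collagen expression by the treated cells, since the whole fibroblast list had a median intensity of 79.8 and a median difference of 0.52.

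Probesets that departed from their gene may be switched exons, probesets that do not follow their gene, or noise. Of the departing probesets, 64.5% (exact 95% interval 63.0% to 66.0%) lay in genes that differed less than 2-fold, which argues against probesets that do not follow a large difference of their gene as the whole cause. They may still be a part, since 12.6% of probesets departed in genes that differed at least 2-fold and 2.62% in the others. The others held 89.7% of the probesets tested. Of the 1399 departing probesets in genes that differed at least 2-fold, 940 departed towards 0. The rate of departing probesets in the brightest of 4 equal groups was 0.146 times that in the dimmest, which is consistent with noise of dim probesets for many of them. The share of splicing-list genes with a departing probeset stood at percentile 76.6 of random lists, but with 38 genes its exact 95% interval (26.3% to 59.2%) spans most of the random range, so switched exons stay open, for Cd44 with 9 of 19 probesets among others.

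The 12 lowest genes held 5 enzymes of conjugation and detoxification, and a hypothesis is that these families were lower beyond the named genes. The other 36 members at level of the Akr, Aldh, Cyp, Gst, Sult and Ugt families had a median of −0.49 against −0.28 in random lists, at percentile 2.13, with 7 at least 2-fold lower and 1, Aldh1l1 (1.19, named after its value was seen), higher. Centring moves the families and the random lists alike, so its percentile of 1.78 differs only through new random draws. The percentile was 3.80 after quantile normalization (median −0.16) and 6.67 after the lowess (median −0.14), both within the random range. From probesets at level the percentile was 0.46 with 10 at least 2-fold lower, among them Gstm1 (−1.92, but −0.39 at gene level), Gstm2 (−1.50, but 0.29) and Aldh4a1 (−1.09, but −0.59), all named after their values were seen. A lower level across these families could therefore not be separated from the trend of difference on level.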
